A study of Drosophila melanogaster with 4 samples.

How the data were processed

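Total RNA from Drosophila melanogaster larvae was compared on 4 two-colour oligonucleotide arrays. Each array held 1 sample of the invadolysin allele 4Y7 and 1 sample of the Canton S wild type. Per the labels, RNA was taken with TRIzol, made into cDNA and labelled with Cy3 or Cy5 by Klenow extension, and stocks were kept at 25 degrees. The mutant was in Cy5 on replicates 1 and 4 and in Cy3 on replicates 2 and 3. The series describes these as 4 biological replicates, and each array was taken as 1 replicate.

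The deposited values were 1 log ratio per probe and array, treated here as log2 ratios. The base, the centring, the within-array normalization and the direction of the deposited log2 ratios are not given in the sources used here. The base was taken as 2 because values reached -13.22, which on a natural or decimal log scale would pass the range of a usual scanner. No channel brightness was used here, so background, clipping and trends with brightness could not be examined, and the number of arrays limits the precision. The column medians of replicates 1 to 4 were -0.0015, 0.0042, 0.0128 and -0.0005, so the arrays were already centred close to 0. There were 0 missing values and 0 identical values between arrays.

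The direction was set by a rule fixed before the data were examined. Arrays of opposite dye orientation correlated positively over probes (mean Pearson r = 0.217), above the rule's bound of 0.1, so the values were taken as already turned to mutant over wild type, as the titles word the comparison. The correlations of the opposite pairs were 0.401, 0.397, 0.031 and 0.039, and those of the same-orientation pairs were 0.213 and 0.651. The rule's outcome turns on replicate 1: without it the mean of the opposite pairs was 0.035, under the bound, where the rule would have turned the swapped arrays and given counts both ways. The 2 pairs left without replicate 1 both hold replicate 4. Without replicates 2, 3 and 4 the mean was 0.218, 0.216 and 0.399. These are correlations across genes, which are not independent replicates. That all arrays run the same way rests on these values, which a dye bias of the probes in unturned ratios could also give, and that higher means higher in the mutant is likely from the titles only.

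Of 14569 probes, 12658 had 1 gene symbol in the platform annotation, 96 had several and 1815 had none. The annotation can be old, and matching 12012 probes to a current gene table renewed 0 symbols. Probes of 1 gene were averaged per array (436 genes had more than 1 probe). This left 11980 named genes and 1911 probes without a single name, 13891 features in all. The gene table, of the Release 6 plus ISO1 MT assembly, served only for names, chromosome arms and neighbours.

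Each feature's log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, prior degrees of freedom 3.275), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 28 gene lists, fixed before the data were examined, were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. Lists needed 5 measured genes. Many list members had no singly named probe, so a list stands for its measured genes. Chromosome arms were compared by Fisher's exact test. SDs are over the 4 arrays. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

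The genes named are Invadolysin, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with the same sign on all 4 arrays, 3 more per direction among genes known by number only, and up to 4 members of each list with the smallest p. Within that limit, how many members of each list to print was settled after the values were seen. Further genes were named after their values were seen, and the text says so where they appear.

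The steps were tested on simulated data with 13891 features and 4 arrays. In the comparison of mutant with wild type, the test recovered 0% of features changed 1.5-fold, 34% of those changed 2-fold, 94% of those changed 4-fold and 100% of those changed 8-fold. Of the 119 calls in that simulation, 4.2% were unchanged features. The simulated noise was normal, with 1 SD per feature shared by all 4 arrays. In the data the arrays differed, with array weights from 0.23 to 5.47. These shares are therefore those of the simulation and not the power or error rate of this experiment. Camera gave a simulated list of 60 genes shifted by 0.5 log2 an adjusted p of 4.33e-21, and 1 of 100 unshifted lists passed an unadjusted p of 0.05. The simulated features varied independently of each other, so this cannot show how often camera passes unshifted lists of correlated genes. In the data, the estimated correlations of the 9 lists past camera ran from -0.039 (salivary glue) to 0.377 (muscle), with 0.104 for the mitochondrial ribosome.

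The alternatives were a dye term, centring, scale and quantile normalization between arrays, a robust prior, the other coding of the ratios, single probes, each array left out, an ordinary t statistic without eBayes, and treat with a minimum fold of 1.2. Keeping only genes present on all 4 arrays removed nothing. Array weights, the digestive list without 3 stray members, and leaving out features over 5 in size were chosen after seeing the data.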

Results

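The series compared gene expression in larvae mutant for invadolysin, which encodes a conserved zinc metalloprotease, with that of Canton S wild-type larvae. Each of the 4 arrays set 1 mutant against 1 wild-type sample, with the mutant in Cy5 on 2 arrays and in Cy3 on 2. Values are log2 ratios of mutant over wild type. This direction is likely rather than stated, since it rests on the wording of the titles. If it were the opposite, every "higher" below would read "lower". That the swapped arrays were already turned is inferred from correlations between arrays of opposite orientation (mean r over probes 0.217, but 0.035 without replicate 1), which a dye bias of the probes in unturned ratios would also give. In unturned ratios a value of one sign on all arrays would be a dye effect, and with that coding limma called 0 features (1053 at an unadjusted p under 0.05) and camera 0 lists. Dye orientation was the batch known here, and both orientations are given where a comparison leads.

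Genes of immune effectors were higher in the mutant larvae (camera adjusted p = 2.13e-07; adjusted p = 0.272 with an estimated correlation), single genes of Hsp70 and the GstD glutathione transferases rose, and among the genes that fell furthest were Cht9, Alp7 and PGRP-SC2. The immune peptide gene DptB, a diptericin, rose 10.8-fold (log2 3.43 ± 0.68, SD, n = 4), and Hsp70Ba, a heat shock chaperone gene, rose 5.99-fold (log2 2.58 ± 0.31). Cht9, a chitinase-family gene, fell by 3.34 ± 0.89 and Alp7, an alkaline phosphatase gene, fell by 3.01 ± 0.31 on the log2 scale. Genes of the mitochondrial ribosome and the respiratory chain lay lower as groups (camera adjusted p = 1.75e-21 and 1.5e-15; adjusted p = 0.272 and 0.391 with an estimated correlation). In limma, 114 of 13891 features changed at the threshold of 0.05, 55 higher and 59 lower, and 100 of these were named genes (46 higher, 54 lower). All 114 had the same sign on all 4 arrays and changed more than 2-fold. With 4 arrays a call at this threshold nearly requires both, so neither is separate support. Of all tested features, 28.93% had the same sign on all 4 arrays.

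The Invadolysin probe itself did not differ detectably between mutant and wild type. Its log2 ratio was 0.10 ± 0.16 (SD, n = 4; limma adjusted p = 0.761), with values of -0.12, 0.11, 0.16 and 0.25 on replicates 1 to 4. The lesion of 4Y7 is not given in the sources used here, so whether the probe lies in the altered part is unknown and it is no check on the labels.

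Among named genes the largest rises were those of Bbd (log2 3.48 ± 0.91), DptB, RFeSP (3.23 ± 0.51) and Gr22c (3.14 ± 0.99). Bbd was a member of the antimicrobial peptide and recognition list. RFeSP encodes the Rieske iron-sulphur subunit of respiratory complex III, and Gr22c is a gustatory receptor gene. The genes mat (2.87 ± 0.48), Rdh1 (2.78 ± 0.47) and Srg2 (2.72 ± 0.35) also rose. BomS2 (2.79 ± 0.33) and BomT3 (2.20 ± 0.65), both bomanin peptide genes, Drs (2.58 ± 0.73), the drosomycin gene, and Hsp70Bbb (2.38 ± 0.67) complete the 12. Adjusted p in limma lay between 0.014 and 0.0424 for these 12 genes. Copies of Hsp70, bomanins and GstD genes are similar in sequence, and their probes may share hybridization, so which copy changed is uncertain. Of genes known by number only, CG30029 (3.21 ± 1.13), CG14424 (2.33 ± 0.83) and CG12934 (2.23 ± 0.65) rose most.

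The largest falls after Cht9 and Alp7 were those of PGRP-SC2 (-2.78 ± 0.63), which encodes a peptidoglycan-degrading amidase, AANATL4 (-2.42 ± 0.81), TwdlO (-2.28 ± 0.64), a cuticle protein gene of the Tweedle family, and Jig (-2.18 ± 0.78). Smaller falls were found for sel (-1.65 ± 0.26), Prosalpha1R (-1.54 ± 0.22), Fnta (-1.50 ± 0.33), Caf1-55 (-1.49 ± 0.29), a histone-binding chromatin protein gene, Sec61gamma (-1.47 ± 0.43), a subunit of the translocon, and EndoGI (-1.44 ± 0.36), an endonuclease inhibitor gene. CG10474 (-1.99 ± 0.61), CG2233 (-1.86 ± 0.22) and CG13678 (-1.77 ± 0.50) fell most among genes known by number. Under quantile normalization the calls of Cht9, Alp7, PGRP-SC2, AANATL4, TwdlO, Sec61gamma and CG13678 were lost, with limma adjusted p = 0.0611, 0.0513, 0.0602, 0.076, 0.0895, 0.065 and 0.113. Their mean log2 ratios were then further from 0, at -4.29 ± 2.07, -3.65 ± 1.51, -3.72 ± 1.75, -3.43 ± 1.95, -2.78 ± 1.73, -1.59 ± 0.70 and -2.29 ± 1.67, and their spread between arrays was larger. Under scale normalization those of Jig, Sec61gamma, CG10474 and CG13678 were lost (limma adjusted p = 0.0524 for each), at log2 ratios of -2.22, -1.49, -2.02 and -1.81. Those of Jig and Sec61gamma were also lost with probes tested singly (limma adjusted p = 0.0512 and 0.0516), at log2 ratios of -2.18 and -1.47.

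**Figure D1:**
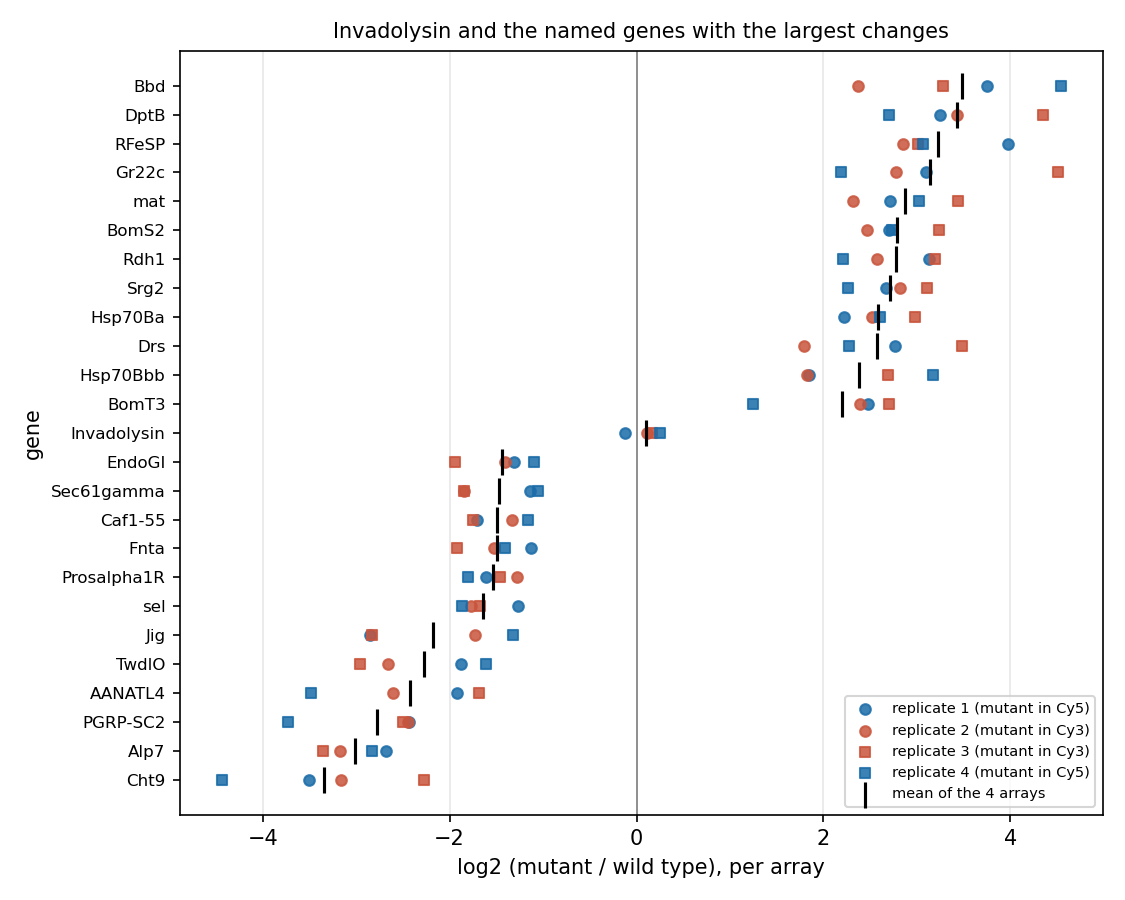
Log2 ratio of mutant over wild type (horizontal axis) for Invadolysin and the 24 named genes of largest change (vertical axis), 1 point per array, coloured by the dye of the mutant, with a bar at the mean of the 4 arrays. The genes were chosen for points on 1 side of 0 on all 4 arrays, while those of Invadolysin run from -0.12 to 0.25.

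The count of changed genes rested on few arrays, and replicate 4 stood apart, with r over probes of 0.213, 0.031 and 0.039 with replicates 1, 2 and 3. With a separate dye term limma called 0 features (3537 at an unadjusted p under 0.05, against 2670 without the term). With balanced dyes this term leaves the log2 ratios unchanged by construction, such as 3.43 for DptB and -3.01 for Alp7. Without replicates 1, 2, 3 and 4 limma called 0, 19, 17 and 21 features, with 2052 at an unadjusted p under 0.05 without replicate 1. Of the calls without replicates 2, 3 and 4, 17, 16 and 15 were among the 114. An ordinary t statistic called 1 feature, not among the 114, and treat called 22, all among them. Under quantile normalization 61.1% of 90 calls were higher, against 48.2% of the 114, and the calls were 17 higher and 2 lower without replicate 2, 14 and 3 without replicate 3, 16 and 5 without replicate 4, 17 and 5 with treat, and 85 and 132 without features over 5 in size. Within dye orientations of 2 arrays each, limma called 4 features with the mutant in Cy5 and 2573 with it in Cy3.

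Antimicrobial peptide and recognition genes were higher as a group. Of 28 measured members 9 rose and 1 fell, 18 did not pass, and adjusted over the list alone 16 rose and 2 fell. The list's mean log2 ratio was 0.82 ± 0.27 (SD of array means, n = 4), with a median of 0.78 (camera adjusted p = 2.13e-07; adjusted p = 0.272 with an estimated correlation). BomS2, DptB, Bbd and Drs were among those that rose, and PGRP-SC2 was the member that fell. PGRP-SB1 (2.20 ± 0.50), Def (1.77 ± 0.36), the defensin gene, AttB (1.65 ± 0.25) and AttD (1.204 ± 0.24), both attacin genes, and LysX (1.53 ± 0.48), a lysozyme gene, rose too and were named after their values were seen. The calls of AttD and LysX were lost under scale normalization (limma adjusted p = 0.0522 and 0.0585, log2 1.21 and 1.58). Both were also lost with probes tested singly (limma adjusted p = 0.0512 and 0.0516, log2 1.2 and 1.53), and that of LysX under quantile normalization (0.0584, log2 1.52). The list's median was 0.69 over the arrays with the mutant in Cy5 and 0.52 over those with it in Cy3.

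Genes of mitochondrial translation and respiration lay lower in the mutant. Of 69 mitochondrial ribosomal genes 0 rose and 1, mRpS16 (-1.32 ± 0.13), fell, and adjusted over the list alone 46 fell. Their median log2 ratio was -0.74 and their mean -0.73 ± 0.28 (camera adjusted p = 1.75e-21; adjusted p = 0.272 with an estimated correlation). Next by p were mRpS2 (-1.05 ± 0.14) and mRpS10 (-1.14 ± 0.24), which did not pass over all genes. Of 60 respiratory chain and ATP synthase genes 1, RFeSP, rose and 0 fell, and adjusted over the list alone 1 rose and 32 fell. The median of this list was -0.60 and the mean -0.55 ± 0.18 (camera adjusted p = 1.5e-15; adjusted p = 0.391 with an estimated correlation). COX8 (-1.13 ± 0.22) and COX6B (-1.005 ± 0.07), subunits of cytochrome c oxidase, had limma adjusted p = 0.0524 and 0.0543. Over the arrays with the mutant in Cy5 and in Cy3, the median of the mitochondrial ribosome list was -0.60 and -0.93, and that of the respiratory list was -0.43 and -0.80.

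Genes of the tricarboxylic acid cycle and glycolysis were lower as groups, with no single member past the threshold over all genes. In the cycle, 0 of 14 genes rose or fell over all genes and 9 fell adjusted over the list alone, with a median of -0.60 and a mean of -0.52 ± 0.26 (camera adjusted p = 0.000112; adjusted p = 0.453 with an estimated correlation). SdhC (-0.84 ± 0.14) and SdhD (-0.81 ± 0.21), subunits of succinate dehydrogenase, and CG7430 (-0.92 ± 0.28) had the smallest p. The respiratory chain list also holds the succinate dehydrogenase genes, so these lists overlap. Of 10 glycolytic genes 0 passed over all genes and 2 fell adjusted over the list alone, with a median of -0.36 and a mean of -0.42 ± 0.18 (camera adjusted p = 0.0104; adjusted p = 0.453 with an estimated correlation). Values were -1.03 ± 0.18 for Ald1, the aldolase gene, -0.67 ± 0.28 for Tpi and -0.72 ± 0.70 for Gapdh1.

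Muscle genes, markers of a tissue that whole larvae hold, were also lower as a group. Of 22 genes 0 passed over all genes and 0 adjusted over the list alone, with a median of -0.63 and a mean of -0.66 ± 0.42 (camera adjusted p = 3.14e-06; adjusted p = 0.453 with an estimated correlation). Msp300 was at -1.03 ± 0.61, SERCA at -0.61 ± 0.21 and up, the troponin T gene, at -0.65 ± 0.35. The muscle median was -0.36 with the mutant in Cy5 and -0.94 with it in Cy3, and on replicates 1 to 4 it was -0.61, -0.80, -1.13 and -0.05. On replicate 4 the medians of the mitochondrial ribosome, respiratory chain and tricarboxylic acid cycle lists were -0.46, -0.67 and -0.46. Genes of the salivary glue list, which also takes in the Eig71E genes, were higher as a group. Of its 18 measured genes, 0 passed the threshold over all genes and 2 rose adjusted over the list alone. Their median was 0.43 and their mean 0.57 ± 0.23 (camera adjusted p = 0.000455; adjusted p = 0.272 with an estimated correlation). The values of ng2, ng3 and Sgs4 were 1.77 ± 0.74, 0.98 ± 0.43 and 1.59 ± 1.15.

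Genes of the cell death and DNA damage list, which also holds the Atg autophagy genes, lay slightly higher and chromatin genes slightly lower. In the first list 0 of 42 genes passed over all genes and 0 adjusted over the list alone, with a median of 0.21 and a mean of 0.19 ± 0.18 (camera adjusted p = 0.042; adjusted p = 0.453 with an estimated correlation). mre11 (1.32 ± 0.54), Atg8a (1.21 ± 0.61) and rad50 (0.77 ± 0.48) had the smallest p. Of 19 histone and chromatin genes 0 rose and 1, Caf1-55, fell, and adjusted over the list alone 2 fell, with a median of -0.18 and a mean of -0.27 ± 0.14 (camera adjusted p = 0.0493; adjusted p = 0.453 with an estimated correlation). His2Av was at -0.69 ± 0.17 and the gene for the large subunit of chromatin assembly factor 1 at -0.38 ± 0.31. Both list calls were lost without replicate 2 (camera adjusted p = 0.125 and 0.124, medians 0.14 and -0.12) and without replicate 3 (0.0977 and 0.137, medians 0.12 and -0.07), and that of the chromatin list with probes tested singly (0.182).

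**Figure D2:**
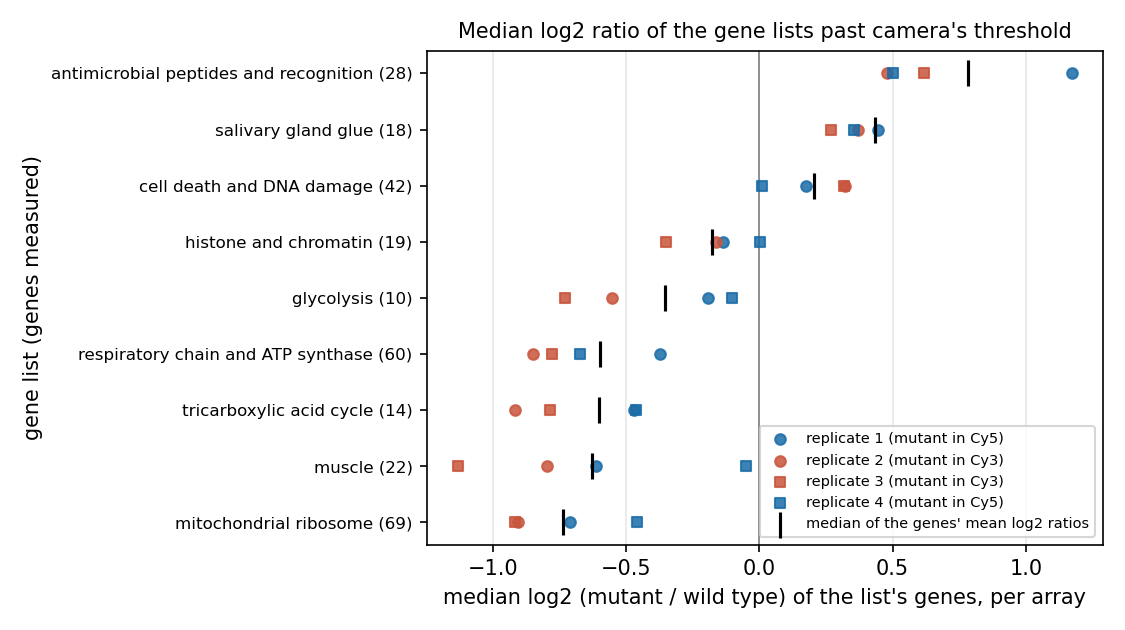
Median log2 ratio of mutant over wild type (horizontal axis) of the 9 gene lists past the camera threshold (vertical axis, with the number of genes measured), 1 point per array, coloured by the dye of the mutant, with a bar at the median of the genes' mean ratios. The mitochondrial ribosome list lies between -0.92 and -0.46 and the antimicrobial list between 0.48 and 1.17 on the 4 arrays.

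Of the 28 lists, 9 passed camera, 6 lower and 3 higher, and 0 passed with an estimated correlation, so these camera calls rest on the preset correlation. Fry presets no correlation and tests whether a list's genes move one way on balance, without comparing them with other genes. It passed 4 of the 9 lists: mitochondrial ribosome (fry adjusted p = 0.0289), respiratory chain (0.0375), antimicrobial (0.0289) and salivary glue (0.0289). Its mixed test, for change in either direction, passed 20 of the 28.

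Single genes changed in lists that did not pass camera. Among 138 detoxification genes 5 rose and 0 fell, and adjusted over the list alone 13 rose and 8 fell, with a median of 0.06. The glutathione transferase genes GstD3 (1.68 ± 0.27), GstD9 (1.87 ± 0.40) and GstD6 (1.71 ± 0.33) rose, as did GstD2 (1.54 ± 0.46) and the glucuronosyltransferase gene Ugt49C1 (1.30 ± 0.29), the last pair named after their values were seen. The call of GstD2 was lost with probes tested singly (limma adjusted p = 0.0512, log2 1.54). Among 33 heat shock and oxidative stress genes 3 rose, Hsp70Ba, Hsp70Bbb and Hsp27 (1.16 ± 0.07), and 0 fell, while adjusted over the list alone 5 rose and 11 fell. That list's median of -0.12 and mean of 0.03 differed in sign. Of 139 cuticle genes 1, Cpr47Eb (2.01 ± 0.64), rose and 3 fell, Cht9, TwdlO and Cpr78Ca (-1.10 ± 0.15), the last named after its value was seen. The call of Cpr78Ca was lost under scale normalization (limma adjusted p = 0.055, log2 -1.11), quantile normalization (0.0584, log2 -1.11) and with probes tested singly (0.0516, log2 -1.1). Adjusted over the list alone 8 cuticle genes rose and 20 fell (median -0.06).

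In the lipid storage and synthesis list 0 of 23 genes rose and 2 fell, Gpdh1 (-1.43 ± 0.35), the glycerol-3-phosphate dehydrogenase gene, and Lsd-1 (-1.25 ± 0.22), which encodes a lipid droplet perilipin. Adjusted over the list alone 1 rose and 6 fell, with a median of -0.35 (camera adjusted p = 0.0527), and FASN1, a fatty acid synthase gene, was at -0.94 ± 0.30. Of 24 ribosome biogenesis genes 1, Non1 (1.33 ± 0.13), rose and 0 fell, and adjusted over the list alone 1 rose, with a median of -0.27 (camera adjusted p = 0.0527). CG7246 was at -0.73 ± 0.37 and Nop56 at -0.73 ± 0.41. Of 13 fatty acid oxidation genes 0 passed over all genes and 1 rose and 2 fell adjusted over the list alone (median -0.39), with Echs1 at -1.14 ± 0.34.

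The remaining 13 lists had 0 members past the threshold over all genes and did not pass camera. Of 40 cytoplasmic ribosomal genes (median -0.14) and 35 DNA replication genes (median -0.11), 0 passed adjusted over the list alone, with qm at 0.75 ± 0.25 and PCNA at -0.92 ± 0.30. The gene qm encodes a prenyl synthase and entered the ribosomal list through a former name of a ribosomal protein gene. Of 34 mitosis genes 1 rose and 1 fell adjusted over the list alone (median -0.02), and Nuf2 was at -1.77 ± 0.88. Of 18 SAGA complex genes 0 passed adjusted over the list alone, with Ada1-1 at 0.74 ± 0.33, and the median of -0.04 went against the test's upward direction. Blood cell markers (25 genes, median -0.05, ItgaPS4 0.66 ± 0.10), imaginal disc genes (32, median -0.03, Ance -0.76 ± 0.53), testis and germ line genes (50, median 0.04, Tektin-A 0.59 ± 0.17) and fat body and serum protein genes (11, median -0.14, Obp99a 0.32 ± 0.41) had 0 past adjusted over the list alone. The ecdysone list (28, Cth -0.84 ± 0.42) also had 0, and its median was 0.004 while its mean was -0.01. Adjusted over the list alone 1 Turandot and JAK-STAT gene of 10 rose (median 0.05, Tep4 0.82 ± 0.22), 1 nervous system gene of 30 rose (median 0.11, ple 1.16 ± 0.37), and 2 insulin and TOR genes of 17 rose while 1 fell (median 0.05, InR 1.02 ± 0.50). The digestive enzyme list (55 genes) took in stray members, among them SerRS, SerT and Serinc, through the start of their symbols. Adjusted over the list alone 1 of its genes rose and 10 fell (median -0.10, Jon99Fi -1.23 ± 0.45). The list's medians on replicates 1 to 4 were 0.39, -0.25, 0.33 and -1.11.

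Changed genes were not detectably concentrated on a chromosome arm. Arm 2R held 29 changed genes of 2336 tested, against 68 of 9032 elsewhere (odds ratio 1.66, Fisher's exact test, two-sided, adjusted p = 0.185). Within 1 Mb of Invadolysin on arm 3R, 0 genes changed, against 97 of 11163 elsewhere (Fisher's exact test, two-sided, p = 0.425). Without replicate 2, arm 2R passed (Fisher's exact test, adjusted p = 0.0302), and it did so too with probes tested singly (0.0398) and without features over 5 in size (0.0351).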

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

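All tests weighed in this part were chosen after the result was seen, except the test of neighbouring genes for the immune pattern and the counts over other assignments. Of 125 results checked for 1 array far from the other 3, 4 were found, and chance gives about 1 in 20. PGRP-SC2 was at -3.73 on replicate 4 and between -2.5 and -2.44 on the others. The gene for the large subunit of chromatin assembly factor 1 was at -0.84 on replicate 2 and between -0.29 and -0.19 on the others. The median of the blood cell list was 0.01 on replicate 1 and between -0.12 and -0.09 on the others. The median of the ecdysone list was 0.2 on replicate 3 and between -0.08 and -0.05 on the others.

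Turning single arrays gives 8 assignments of mutant and wild type, too few for a share under 0.05. The real assignment gave 114 changed features, and 1 of the 8, itself, gave as many, the highest other being 0. For the gene lists the real assignment gave 9, 5 of the 8 gave as many and the highest other gave 13. That highest one turned replicate 4, which correlated at 0.031 and 0.039 over probes with replicates 2 and 3, and it gave 0 changed features with 2096 at an unadjusted p under 0.05 in limma. The assignment that follows the dyes, which is also the other coding of the ratios, gave 0 features and 0 lists.

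The lower level of the 3 mitochondrial lists may reflect the mutation, the makeup of the larvae or the measurement. The respiratory chain and tricarboxylic acid cycle lists share the succinate dehydrogenase genes, so these lists are not fully separate evidence. The least negative of the 12 array medians was -0.372, but one sign on all arrays speaks against a dye effect only if the swapped arrays were already turned, which is not stated, and with the other coding the mitochondrial ribosome and respiratory medians were 0.18 and 0.13, so a dye effect stays open. A shift growing with brightness would lower the abundant cytoplasmic ribosomal genes at least as far, yet the mitochondrial ribosome mean lay below theirs by a difference of -0.563 ± 0.149 (SD over arrays). That comparison assumes bright spots were not clipped, which was not examined, and it rests on 1 comparison list. Among gene families outside the lists, the Gr and Ir receptor genes lay higher (median 0.23 each). The Prosalpha and EMC genes lay lower (-0.59 and -0.55). Whether these follow brightness could not be examined, so a trend with brightness is not excluded. A smaller share of muscle stays open, since the mitochondrial mean minus the muscle mean was 0.03 ± 0.258, although on replicate 4 the muscle median was -0.05 and the mitochondrial medians lay between -0.67 and -0.46, and so does a general delay of growth, which was not tested.

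The higher level of immune peptide genes may be a response to the mutation, an infection of the cultures or a difference in background between the mutant stock and Canton S. A dye effect stays open for the same reason: the lowest of the 4 array medians was 0.477, and with the other coding the list's median was 0.08 (camera adjusted p = 0.992). The 90 nearest tested genes outside the list, 5 on each side of the 9 risen members, had a median log2 ratio of 0.094 ± 0.058 (bootstrap SD) and 1 of them changed. This is under the 0.2 that a regional difference was taken to need, and it meets the bound of 0.1 set beforehand for excluding one. That bound made no allowance for the spread. With its spread the median does not clear 0.1, so a regional difference stays open. All mutant samples carried 4Y7 and all controls were Canton S. The 2 stocks' backgrounds therefore cannot be told apart from the mutation by this design, whatever the neighbours show. Infection was not tested.

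RFeSP rose while its list lay lower. A regional background difference would shift its neighbours too, and the 10 nearest tested genes had a median of 0.212 ± 0.128, with values from -0.312 to 0.478 and 0 changed. The highest neighbour lay far below the 3.23 of RFeSP, which argues against a regional shift of that size shared by these genes. The bound for excluding a regional difference was 0.3, which the median met, though not by its spread, so a smaller regional shift stays open. A sequence difference under its single probe was not tested, and a dye effect stays open as for the lists.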

How the results depend on the processing

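The number of changed features (114) was 116 with centring, 99 with scale and 90 with quantile normalization, 118 with a robust prior and 91 with single probes, sharing 114, 91, 83, 114 and 89 with the 114. It was 0 with a dye term (smallest limma adjusted p = 0.0509, 3537 at an unadjusted p under 0.05), where fewer residual degrees of freedom remain, 1 with an ordinary t statistic, which has no shared prior, and 22 with treat, which asks for a minimum fold. Leaving out each array gave 0 to 21 calls, with fewer arrays in each fit, and 76.2% to 89.5% of the calls without replicate 2, 3 or 4 were higher. Chosen after seeing the data, array weights of 0.52, 5.47, 1.51 and 0.23 for replicates 1 to 4 gave 6079 calls, a count that rests mainly on replicate 2, and leaving out features over 5 in size gave 217; the cause was not tested. The gene list count (9) was 0 with an estimated correlation, 4 with fry, 20 with its mixed test and 8 to 13 without single arrays, with the cause not tested. The number of arms (0) was 1 with single probes, 1 without features over 5 in size and 0 to 1 without single arrays; the cause was not tested. Among lists that passed in neither setting, the direction of the fat body list turned under scale (median -0.06) and quantile normalization (0.22) and array weights (-0.07), that of the mitosis list under array weights (-0.05) and that of the ecdysone list with single probes (0.00). Without single arrays, direction turned in some fits for fat body (medians -0.35 to 0.29), SAGA (-0.05 to 0.10), mitosis (-0.05 to 0.04) and digestive enzymes (-0.38 to 0.22). Some lists that did not pass came past the camera threshold elsewhere, such as ribosome biogenesis under scale (camera adjusted p = 0.0477) and quantile normalization (0.0475), lipid storage without replicate 1 (0.0291) or 3 (0.0101), and digestive enzymes without replicate 1 (0.0481) or 3 (0.0101). The cytoplasmic ribosome list, the comparison for brightness above, passed as lower without replicate 1 (camera adjusted p = 0.0481) or 4 (0.0352) and with array weights (0.023). Depth is limited by 4 arrays without channel brightness, so signal over background is unknown.

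The other coding of the ratios, which treats them as dye ratios, called 0 genes (1053 at an unadjusted p under 0.05 in limma) and 0 lists, and turned signs by its construction, since it subtracts one dye orientation from the other. Invadolysin was then at -0.04. Other log2 values that turned were DptB -0.45, Gr22c -0.50, mat 0.00, BomS2 -0.07, Rdh1 -0.11, Srg2 -0.25, Hsp70Ba -0.17, Drs -0.06, BomT3 -0.34, Alp7 0.25, TwdlO 0.53, Jig 0.09, sel 0.08, Fnta 0.23, Caf1-55 0.05, Sec61gamma 0.37, EndoGI 0.23, CG2233 0.08, CG13678 0.15, COX8 0.16, COX6B 0.05, mRpS16 0.02, qm -0.21, SdhC 0.08, CG7430 0.17, SdhD 0.18, Gapdh1 0.60, Gpdh1 0.12, Lsd-1 0.02, FASN1 0.01, Nuf2 0.00, Ada1-1 -0.18, His2Av 0.02, the gene for the large subunit of chromatin assembly factor 1 0.18, Tep4 -0.16, ItgaPS4 0.00, Obp99a -0.22, Cth 0.33, Cpr47Eb -0.17, Jon99Fi 0.13, GstD3 -0.21, GstD9 -0.13, Hsp27 -0.01, InR -0.37, Atg8a -0.47, rad50 -0.40, Msp300 0.45, SERCA 0.08, up 0.11, ple -0.02, Non1 0.00, CG7246 0.01, Tektin-A -0.02, AttD -0.07, GstD2 -0.25, Cpr78Ca 0.03, Idgf1 -0.43, Idgf4 0.07, Tapdelta 0.19, AGBE 0.08, Galk 0.05, Gdh 0.04, Ahcy 0.04, BNIP3 -0.12. List medians whose test turned were respiratory chain and ATP synthase 0.13, mitochondrial ribosome 0.18, cytoplasmic ribosome 0.20, tricarboxylic acid cycle 0.18, glycolysis 0.21, fatty acid oxidation -0.08, DNA replication 0.15, mitosis 0.01, SAGA complex -0.18, histone and chromatin 0.14, fat body and serum proteins 0.10, salivary gland glue 0.01, detoxification 0.00, cell death and DNA damage -0.15, muscle 0.42, nervous system -0.04, ribosome biogenesis 0.00, testis and germ line 0.04.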

Other observations

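The following single genes outside the lists passed the test and were named after their values were seen, so they stand for no group. BomBc3 (log2 2.05 ± 0.37, SD, n = 4), a bomanin gene, Listericin (1.49 ± 0.21) and Fadd (1.82 ± 0.53), an adaptor of the Imd pathway, rose in limma (adjusted p = 0.0295, 0.0348 and 0.0447). The chitinase-like growth factor gene Idgf1 rose (1.93 ± 0.50) and its relative Idgf4 fell (-1.41 ± 0.27). AGBE (-1.22 ± 0.10), the glycogen branching enzyme gene, Galk (-1.40 ± 0.22), the galactokinase gene, Gdh (-1.28 ± 0.17), the glutamate dehydrogenase gene, and Ahcy (-1.30 ± 0.31) fell. Tapdelta (-1.24 ± 0.24), a translocon-associated protein gene, fell, and BNIP3 (1.64 ± 0.26), a mitophagy receptor gene, rose. The call of Ahcy was lost under scale and quantile normalization and with probes tested singly (limma adjusted p = 0.0524, 0.0546 and 0.0512), at log2 ratios of -1.32, -1.30 and -1.30. That of Tapdelta was lost under quantile normalization (0.0546, log2 -1.27).

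Families sharing a symbol stem, with 8 or more genes outside the lists, were tested by camera, and 9 of 59 passed, 5 lower and 4 higher, while 0 passed with an estimated correlation (smallest adjusted p = 0.507). The proteasome alpha genes (Prosalpha, 10 genes) had a median of -0.59, the EMC genes (9) -0.55, the Sec genes (17) -0.36, the Alp genes (12) -0.32 and the Nup genes (20) -0.26. The Osi genes (24) had a median of 0.39, the Ir genes (52) 0.23, the Gr genes (56) 0.23 and the Spn genes (25) 0.22. The hypothesis of a shared change of a family thus found 0 families under its test. The bound set beforehand counted 0 against the hypothesis. Of the 28 fixed lists 0 passed that test either. The test therefore cannot tell a bound too strict for 4 arrays from an absence of shifts beyond the correlation between genes. The families that lay higher include the Gr and Ir receptor genes, and whether dim probes lie above bright ones could not be examined.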
